A study of Mus musculus with 8 samples.

How the data were processed

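Granulosa cells were collected from mice of the PGR-A KO strain, 4 libraries from knockout and 4 from wild-type animals, and their mRNA was sequenced. Per the labels, mice of 21 to 27 days received 5 IU eCG and, 46 h later, 5 IU hCG, and cells were taken 8 h after hCG. Cells of 2 to 3 mice were pooled for each library. RNA was extracted with a Monarch kit, libraries were made with a TruSeq stranded mRNA kit, and paired-end reads came from an Illumina NovaSeq instrument, per the labels. Groups and replicate numbers were taken from the sample titles.

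The authors deposited a single table of TPM, a transcript share normalised to a fixed total, with 51886 gene symbols. The submitters' processing notes name FastQC, Salmon, limma and edgeR and the build mm10, without versions or roles. How transcript values were summed to genes, and the annotation, are not given in the sources used here. Each library's TPM sum to between 994519 and 997022. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval is given. An exact 0 in such a table can be a failed estimate and is reported as listed at 0. Gene-level values cannot separate the receptor isoforms of Pgr.

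No counts are in the table, so no count test was run. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend, in 14472 genes with at least 1 TPM in at least 4 of the 8 libraries. The fit held the 4 PGR-A KO and 4 WT libraries and no covariate. Fold changes are KO minus WT on the log2(TPM + 1) scale, which understates the change of low genes. P-values are 2-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Single values were also compared by an exact 2-sided permutation test over the 70 assignments of 8 libraries to 4 and 4, whose smallest possible p is 0.0286.

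Before the data were examined, 19 pathway lists and 10 cell type marker lists were fixed. The 28 lists with at least 3 tested members were compared with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 28 lists. Members were counted over all genes tested and adjusted over the list alone. The genes named were fixed by rule: Pgr; the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap and at least 5 TPM, without Gm numbers, Rik names and pseudogenes; each measured member of the PGR-dependent list; up to 3 called members of each other list in each direction, or else the member with the lowest p; and the most abundant member of each cell type list. Genes outside the rule are said to be so.

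The steps were tested on simulated data: 14472 genes with the means and spreads of the real ones, 200 of them changed. With independent noise, 37.5% of the genes changed by 0.5 on the log2 scale were recovered, and 82.5% of those changed by 1. With a shared component like that of the real residuals these were 42.5% and 75%. Unchanged genes made up 7.56% of the calls with independent noise and 15.5% with the shared component, above the nominal 5%. Each noise type was a single random draw. With 200 genes changed, more calls pass and the cut-off on the unadjusted p is looser than where 2 genes pass. The recovery shares therefore overstate what the real fit could detect if few genes changed.

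Positions are from GENCODE M21 on the mm10 assembly, matched by symbol for 95.2% of the table's symbols. Shared sequence was searched with BLASTN 2.17.0 against the GENCODE M21 transcripts. Alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter, a minimum of 5 TPM, TMM factors computed on the TPM table, quantile normalization, limma with robust empirical Bayes or without trend, a replicate block, each library left out, a log2 change of at least 1, an adjusted p under 0.01, and the other list tests. Array weights, residual components as covariates and a fit without PGR-A KO replicate 3 and WT replicate 1 were added after their effect on the calls had been seen.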

Results

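The progesterone receptor gene Pgr gives rise to the isoforms PGR-A and PGR-B. The design compared granulosa cells of mice lacking PGR-A with wild-type cells 8 h after hCG, the hormone that triggers ovulation. The 4 PGR-A KO and 4 WT libraries correlated with each other at 0.970 to 0.991 on the log2 scale, and no libraries held identical values. P-values measure the spread between pools of mice.

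Pgr (ENSMUSG00000031870.16, chromosome 9, 8899833 to 8968611, plus strand, mm10) was low in both genotypes and higher in the knockout. Its level was 2.96 ± 0.658 TPM (SD, n = 4) in PGR-A KO and 1.15 ± 0.395 TPM (SD, n = 4) in WT. The PGR-A KO libraries held 3.21, 3.52, 2.01 and 3.08 TPM, and the WT libraries 1.56, 0.878, 1.41 and 0.756 TPM. The log2 change was 0.88 (SE 0.18), with an exact permutation p of 0.0286, the smallest this design allows. Over all genes tested by limma the change did not pass, with an adjusted p of 0.445. The value sums all Pgr transcripts, so it neither measures the loss of PGR-A nor checks the labels.

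Lyve1, a hyaluronan receptor known from lymphatic vessels and some macrophages, had the clearest difference between genotypes among the genes named by the rule. Lyve1 (chromosome 7, 110850607 to 110863239, minus strand) stood at 24.3 ± 7.77 TPM (SD, n = 4) in PGR-A KO and 178 ± 61.5 TPM (SD, n = 4) in WT, a ratio of means of 7.30 between WT and KO. The KO libraries of Lyve1 ranged from 18.8 to 35.6 TPM and the WT libraries from 127 to 267 TPM. Its log2 change was -2.81 (SE 0.25, limma adjusted p = 0.00919). Lyve1 did not pass without PGR-A KO replicate 2, PGR-A KO replicate 4 or WT replicate 2, nor without the filter on low values, with an adjusted p of up to 0.0812.

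Of 14472 genes tested with limma, 2 passed the threshold, both lower in the knockout, and 0 were higher. The other was Gm13597 (chromosome 2, 68554555 to 68554929, plus strand), a processed pseudogene named after its values were seen. Gm13597 was listed at 0 in all 4 PGR-A KO libraries and at 6.32, 17.3, 12.1 and 18.9 TPM in WT (limma adjusted p = 0.0034). Its 375 bases match a Tax1bp3 transcript with 100% identity, so its value is uncertain. At an unadjusted p under 0.05 there were 913 genes (6.31%, against 5% given by chance), 141 higher and 772 lower. This split moved to 350 higher and 500 lower with TMM factors and to 385 and 525 with quantile normalization. With a library left out the number of such genes ran from 505 (without PGR-A KO replicate 4) to 1832 (without WT replicate 1), with 65 to 535 higher and 393 to 1427 lower. The count past the threshold was 5, 1, 6 and 1 without PGR-A KO replicate 1, 2, 3 and 4 in turn, and 4, 0, 2 and 1 without WT replicate 1, 2, 3 and 4, where Gm13597 fell under the filter. Without PGR-A KO replicate 3 and WT replicate 1 together, picked by their values, it was 1131. The groups did not overlap in 495 genes (3.42%), against 2.86% given by chance.

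**Figure D1:**
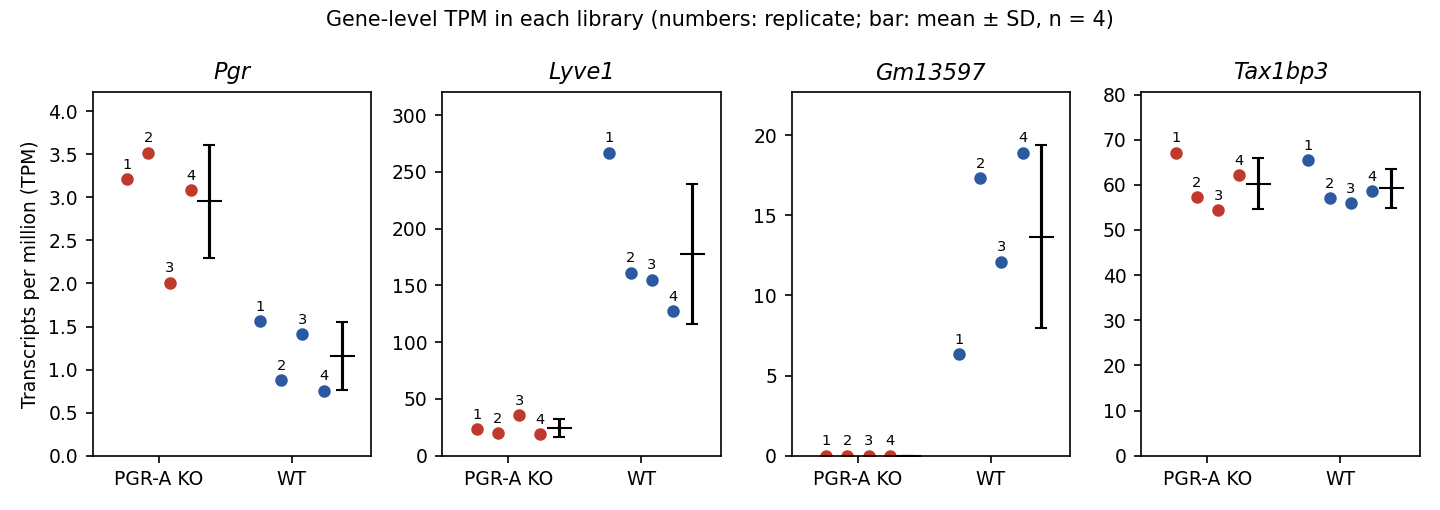
TPM of Pgr, Lyve1, Gm13597 and Tax1bp3 in each library, with PGR-A KO in red and WT in blue; the numbers are replicates and the black bars the mean ± SD of 4 libraries. Lyve1 lies between 18.8 and 35.6 TPM in PGR-A KO and between 127 and 267 TPM in WT, and Gm13597 is listed at 0 in each PGR-A KO library.

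Among genes known to depend on PGR during ovulation, such as the protease gene Adamts1, no gene passed the threshold. Of 25 such genes tested, 19 had higher and 6 lower means in PGR-A KO, and 0 passed over all genes or adjusted over the list alone, where the lowest adjusted p was 0.0513. Adamts1 had 439 ± 152 TPM (SD, n = 4) in KO and 350 ± 140 TPM (SD, n = 4) in WT. The chemokine receptor Cxcr4 had 373 ± 109 TPM (SD, n = 4) in KO and 331 ± 139 TPM (SD, n = 4) in WT. The lowest unadjusted limma p in the list were those of Klf15 (log2 change -0.34, 0.00229), Epas1 (-0.62, 0.0041), Adcyap1 (0.60, 0.0073) and Sult1e1 (0.73, 0.0272). The means of Edn2, Zbtb16, Prkg2, Snap25, Il6, Ctsl, Areg, Ereg, Hif1a, Runx1, Runx2, Rgcc, Fkbp5, Abcb1b and Zfand5 were higher in KO, and those of Pparg, Cited2, Apoa1 and Mt2 lower, with unadjusted limma p from 0.0633 to 0.796. Camera at the preset correlation ranked the list up (adjusted p = 0.0188), but the adjusted p was 0.912 with an estimated correlation, and the call was lost with TMM factors, quantile normalization and no filter, and without PGR-A KO replicate 1 or 4 or WT replicate 3 or 4.

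No gene of the expansion, preovulatory, cholesterol, luteinisation, proliferation or steroidogenesis lists passed the threshold. Of 20 genes of EGF-like factors, prostaglandins and cumulus expansion, 16 had higher means in KO and 0 passed. The EGF-like factor Btc had 54.7 ± 18.9 TPM (SD, n = 4) in KO and 26.6 ± 11.7 TPM (SD, n = 4) in WT (limma adjusted p = 0.752). Of 23 preovulatory granulosa genes, 21 had lower means in KO and 0 passed; Fst, which encodes follistatin, had 456 ± 36.1 TPM (SD, n = 4) in KO and 629 ± 138 TPM (SD, n = 4) in WT (limma adjusted p = 0.738). Higher means in KO were found for 23 of 25 cholesterol genes (Fdft1 had the lowest p), 14 of 18 luteinisation genes (Apoe, itself lower) and 19 of 25 proliferation genes (Ccne2). Steroidogenesis genes were divided, 10 higher and 10 lower, with 0 passing. Camera at the preset correlation ranked the expansion (adjusted p = 0.00289), cholesterol (0.00389), proliferation (0.0188) and luteinisation (0.0188) lists up and the preovulatory list down (0.00389). With an estimated correlation each of these had an adjusted p of 0.912, and fry gave 0.953. Luteinisation was also lost with TMM factors, quantile normalization and without PGR-A KO replicate 1 or 4 or WT replicate 3 or 4; proliferation with quantile normalization, array weights and the first residual component, and without PGR-A KO replicate 2 or 3, WT replicate 1 or 2, or PGR-A KO replicate 3 and WT replicate 1 together; cholesterol without PGR-A KO replicate 1, 2 or 4 or WT replicate 3; and the preovulatory list without WT replicate 2.

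**Figure D2:**
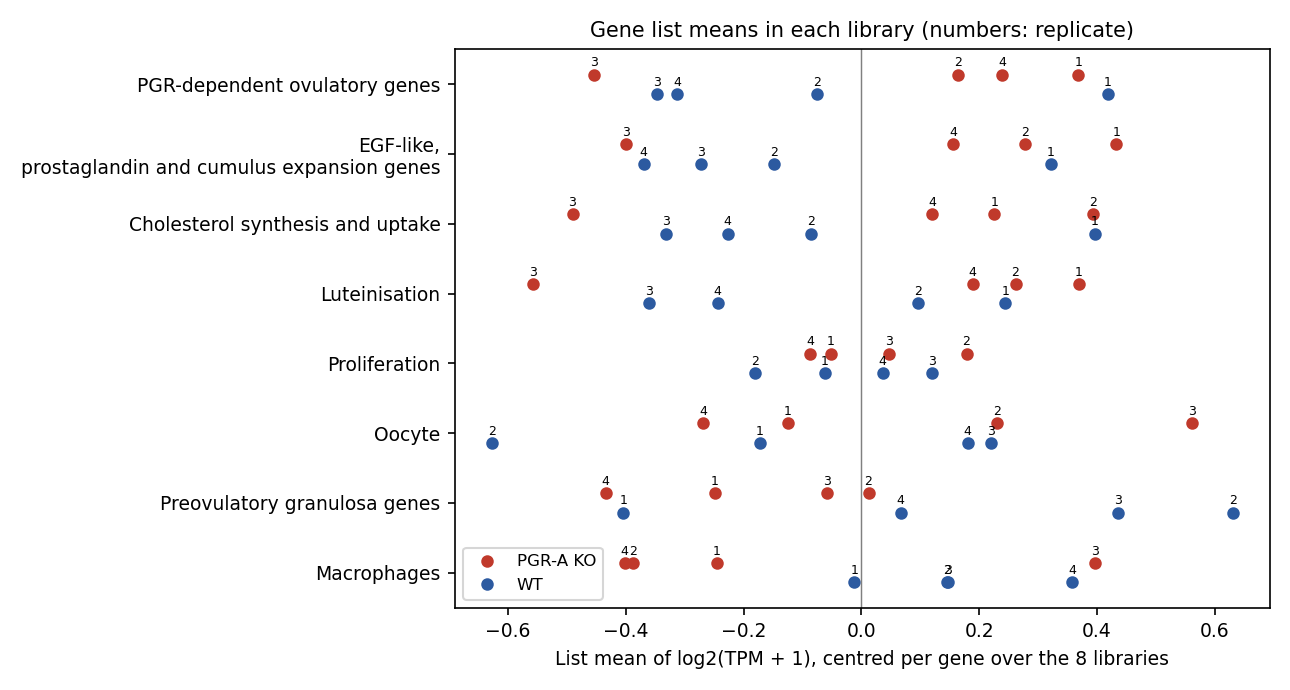
Mean of log2(TPM + 1) over the tested members of each list, centred per gene over the 8 libraries, with PGR-A KO in red and WT in blue and replicate numbers above the points. For the PGR-dependent list, PGR-A KO replicate 3 lies at -0.45 and WT replicate 1 at 0.42, each among libraries of the other genotype.

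Among the other pathways, a few members passed when adjusted over the list alone, none over all genes. These were the protease inhibitor Timp2 at 47.7 ± 2.89 TPM (SD, n = 4) in KO and 67.5 ± 8.16 TPM (SD, n = 4) in WT (limma p adjusted over the list alone 0.0105), the clock output gene Dbp at 6.71 ± 1.18 and 11.2 ± 2.45 TPM (SD, n = 4; 0.0392), and Pgr among steroid receptors and cofactors (0.0198). Higher and lower means were 13 and 8 for proteases and inhibitors, 7 and 9 for the circadian clock, and 11 and 17 for steroid receptors and cofactors. They were 13 and 13 for hypoxia response (lowest p for Bnip3), 5 and 12 for vascular signalling (Ece1), 9 and 5 for cytokines and chemokines (Socs3) and 11 and 15 for adhesion and migration (Cldn1). They were 7 and 16 for PPARG and lipid handling (Pdk4), 7 and 17 for immediate early and heat shock genes (Hspa1b), 2 and 12 for interferon response (Ddx58), 12 and 9 for the unfolded protein response (Herpud1), and 6 and 7 for mitochondrially encoded genes (mt-Nd3). Camera at the preset correlation called none of these lists in the main fit. Alternative fits, some of them also of all 8 libraries, called cytokines, proteases, hypoxia, adhesion and mitochondrially encoded genes up. Such fits called immediate early, PPARG and interferon lists down. For hypoxia, adhesion, steroid receptors and mitochondrially encoded genes camera's direction was up while the median was below 0.

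Markers of other ovarian cells were present in both genotypes. Oocyte markers had higher means in KO for 16 of 16 genes, with Gdf9 at 240 ± 62.2 TPM (SD, n = 4) in KO and 205 ± 55.3 TPM (SD, n = 4) in WT; Padi6 had the lowest p. Macrophage markers had lower means in KO for 10 of 11 genes, with the lysozyme gene Lyz2 at 42.9 ± 18.4 TPM (SD, n = 4) in KO and 57.8 ± 10.7 TPM (SD, n = 4) in WT; C1qc had the lowest p. Camera at the preset correlation ranked the oocyte list up (adjusted p = 0.00289) and the macrophage list down (0.00389); with an estimated correlation both had an adjusted p of 0.912. The oocyte call was lost with array weights and without PGR-A KO replicate 3, WT replicate 2, or PGR-A KO replicate 3 and WT replicate 1 together, and the macrophage call without PGR-A KO replicate 2. All 11 surface epithelium markers (Krt8 had the lowest p and highest level) had lower means in KO. Camera did not call this list in the main fit, but called it with the replicate block and without WT replicate 3. Higher and lower means were 4 and 5 for theca and interstitial cells (Gli1, Aldh1a1), 5 and 5 for stromal fibroblasts (Ogn, Col3a1), 4 and 4 for smooth muscle and pericytes (Tagln, Acta2), 2 and 8 for endothelial cells (Erg, Cdh5), 2 and 2 for neutrophils (Camp) and 5 and 0 for erythroid cells (Alas2, Hbb-bs). Hbb-bs counts as higher by log2(TPM + 1), but its mean was 2035 TPM in KO and 2195 TPM in WT. Without WT replicate 3 camera called the endothelial list down and erythroid cells up. For theca, stromal and smooth muscle markers camera's direction was up while the median was below 0. T and NK cell markers had 2 tested members, Trac and Lck, too few for a list test.

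The largest differences among libraries did not separate the genotypes. The first principal component held 34.9% of the variance, with PGR-A KO replicates 1, 2 and 4 and WT replicate 1 at 20.7, 10.6, 16.4 and 21.2, and PGR-A KO replicate 3 and WT replicates 2, 3 and 4 at -25.8, -3.55, -20.9 and -18.5. No difference between the genotypes was detected along it, with means of 5.46 ± 21.2 (SD, n = 4) in KO and -5.46 ± 19.3 (SD, n = 4) in WT (exact permutation p = 0.486). With 4 libraries in each group this does not show that there is none. The second component held 20.5% of the variance and set WT replicate 2 apart at -35.0, with the other libraries between -1.50 and 14.5. In the list means WT replicate 2 was also the highest library for preovulatory genes (0.63) and the lowest for oocyte markers (-0.63). Mitochondrially encoded genes made up 23.8% ± 3.04 of TPM (SD, n = 4) in KO and 22.6% ± 1.93 (SD, n = 4) in WT (exact permutation p = 0.514).

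**Figure D3:**
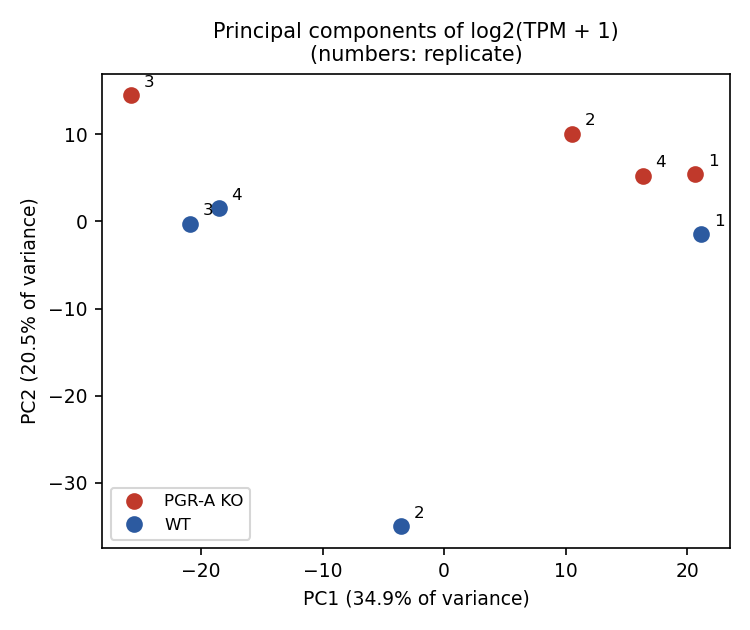
First and second principal components of log2(TPM + 1), each point a library, with PGR-A KO in red and WT in blue and replicate numbers beside the points. WT replicate 1 lies at 21.2 on the first component among 3 PGR-A KO libraries, and PGR-A KO replicate 3 at -25.8 beside 2 WT libraries.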

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

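The tests of the library order and of shared reads in this part were chosen after the result was seen; the counts of other splits were planned. A library lay far from the other 3 of its group in 10 of 123 groups of named genes, where chance gives about 6.15. WT replicate 1 stood apart in Cxcr4 (539 TPM), Zbtb16 (31.9 TPM), Fkbp5 (407 TPM) and Btc (44.2 TPM), above the other WT libraries. PGR-A KO replicate 3 stood apart in Hif1a (140 TPM) and Fkbp5 (280 TPM), below the other KO libraries, and in Lyz2 (70.3 TPM) and Krt8 (30.5 TPM), above them. Ece1 was high in PGR-A KO replicate 2 (510 TPM) and Aldh1a1 in WT replicate 2 (212 TPM).

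PGR-A KO replicate 3 and WT replicate 1 also lie among libraries of the other genotype in ovulatory-response genes. Of the 35 splits of the 8 libraries into 4 and 4, 9 gave 2 or more genes, so chance cannot be excluded for the count of 2; the highest other count was 2397. That split sets PGR-A KO replicates 1, 2 and 4 with WT replicate 1, so the libraries hold a structure much larger than the labelled contrast. For gene lists, 27 of the 35 splits gave 8 or more by camera at the preset correlation. The other splits had a median of 10 lists and a highest count of 19. The count of 8 lists therefore does not exceed what other splits of the libraries gave.

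A swap of labels between PGR-A KO replicate 3 and WT replicate 1 was tested in 3 forms. The first took Lyve1 from all 8 libraries, which is circular, and the second took Pgr, which left the swap open. The third, chosen after these and after Lyve1 was seen to follow the labels, left both libraries out of the choice of genes. That fit called 1131 genes, and Lyve1 had its lowest p and largest log2 change. Lyve1 stood at 35.6 TPM in PGR-A KO replicate 3, below the lowest other WT library (127 TPM). In WT replicate 1 it stood at 267 TPM, above the highest other KO library (23.3 TPM). The gaps were 1.81 and 3.46 on the log2 scale, against an SD within groups of 0.17 over the other 6 libraries. Picking the gene by its lowest p in those libraries favours a small SD, so the gaps set against it can be overstated. Lyve1, a single gene, argues against a swap. In 882 of the 1131 genes both libraries lay on the side of the other genotype, and in 42 both on their labelled side. Both libraries were left out because their values lie with the other genotype. The 882 genes therefore largely restate that order and are not separate evidence for a swap. Pgr lay between the other libraries of the groups at 2.01 TPM in PGR-A KO replicate 3 (0.44 from the nearest other KO and 0.32 from the nearest other WT library on the log2 scale) and at 1.56 TPM in WT replicate 1, there nearer to WT (0.087 from the nearest other WT and 0.67 from the nearest other KO library).

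The order of the libraries itself stays unexplained. A varying share of granulosa cells was taken to make the expansion and preovulatory list means rise and fall together. Over 8 libraries they gave a Pearson r of -0.58 (exact permutation p = 0.141) and a Spearman rho of -0.48 (exact permutation p = 0.243). The r was -0.67 without the 2 libraries farthest out. The sign is opposite to that prediction, but neither p passes, so a varying share stays open. A difference in the stage of the response between mice is a biological alternative that was not tested.

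Gm13597 was listed at 0 in each PGR-A KO library, and reads shared with Tax1bp3 may contribute. Its whole length of 375 bases matches Tax1bp3 with 100% identity in the GENCODE M21 transcripts. Reads that lie within it therefore cannot be told from Tax1bp3 reads by sequence, and its TPM depends on how they were divided. The summed TPM times length of both genes changed by -0.059 on the log2 scale, within the SD of 0.109. This does not decide, since losing the mean Gm13597 share of 5.42% in WT would lower the sum by 0.080, less than that SD. What stays open is a loss of the Gm13597 transcript, a strain variant, or a shift of reads between the copies.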

How the results depend on the processing

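Array weights, residual components and the fit of 6 libraries were chosen after the data, and their effect on the calls, were seen. The 2 genes past the threshold became 3 with a pseudocount of 0.1, 1 with a pseudocount of 5, and between 0 and 6 with a library left out. Lyve1 passed in 17 of 21 alternatives to the fit, and Gm13597 in 15 of the 16 that tested it; with a WT library left out the filter removed Gm13597, which lowers those counts. Lyve1 kept a log2 change between -3.0 and -2.59, with an adjusted p from 0.000247 to 0.0812. Array weights gave 16 genes, the first residual component 36 and the first 2 components 570 (204 higher, 366 lower); components fitted to the same residuals make p too small. Without PGR-A KO replicate 3 and WT replicate 1 together, 6 libraries gave 1131 genes (542 higher, 589 lower); these libraries were picked by their values, so this count does not measure an effect of genotype. The 913 genes at an unadjusted p under 0.05 became 1706 with no filter, 3591 with array weights, 2133 with the first component, 3067 with the first 2 and 3543 with 6 libraries. Pgr stayed higher with an unadjusted limma p under the threshold in each fit that held it, its adjusted p ranging from 0.0107 to 0.998; the minimum of 5 TPM removed it. The 8 lists by camera became 5 with quantile normalization, 0 with an estimated correlation, 0 with fry, and 5 to 11 with a library left out; the cause was not tested. Lists called only in alternatives were, besides those in the last paragraph and under the block, cytokines (up without PGR-A KO replicate 2 or 3 or WT replicate 1 or 4, with array weights, either set of components and 6 libraries), immediate early genes (down without PGR-A KO replicate 1 or WT replicate 3 or 4), proteases (up without PGR-A KO replicate 3, with array weights and 6 libraries) and, without WT replicate 3, PPARG, interferon, endothelial and surface epithelium lists (down) and erythroid cells (up). DESeq2 and voom alternatives were not run because the table holds no counts.

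Residual correlations of same-numbered libraries were 0.36, -0.11, 0.39 and -0.29, and not every library correlated best with its own number. These values show no clear pairing by replicate number. They cannot show that the pools were unmatched, and the labels do not say. The replicate block gave 2 genes and 11 lists, the 8 lists plus cytokines (up), immediate early genes and surface epithelium (both down). The depth is unknown, so low genes such as Pgr have no counting limit here.

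These values changed sign, by median log2 change for lists; the cause was not tested. Camera called the proliferation and oocyte lists in the fit of all libraries, and after the change of sign called hypoxia response and adhesion and migration with array weights and with 6 libraries, and mitochondrially encoded genes without PGR-A KO replicate 2. With array weights per library: Cited2 0.0280, Mt2 0.12, Alas2 -0.0591, Hbb-bs -0.19, Gdf9 -0.0738, hypoxia response 0.0832, vascular signalling 0.00190, adhesion and migration 0.11, proliferation -0.00253, steroid receptors and cofactors 0.0266, PPARG and lipid handling 0.0626, immediate early and heat shock genes 0.0938, unfolded protein response -0.0349, theca and interstitial cells 0.0811, endothelial cells 0.0191, neutrophils -0.39, erythroid cells -0.19, oocyte -0.0954. With 6 libraries, PGR-A KO 3 and WT 1 left out: Cited2 0.0277, Mt2 0.20, hypoxia response 0.0848, vascular signalling 0.0336, adhesion and migration 0.0555, steroid receptors and cofactors 0.0312, PPARG and lipid handling 0.0614, circadian clock 0.00796, immediate early and heat shock genes 0.14, theca and interstitial cells 0.0280. With pseudocount 0.1: Lck -0.000685. With TMM factors on the TPM table: hypoxia response 0.0349, adhesion and migration 0.0302, circadian clock 0.0127, mitochondrially encoded genes 0.0337, theca and interstitial cells 0.0180, stromal fibroblasts 0.0262, smooth muscle and pericytes 0.0307. With quantile normalization: hypoxia response 0.0170, adhesion and migration 0.0170, steroid receptors and cofactors 7.50e-08, circadian clock 0.0301, interferon response 0.00984, theca and interstitial cells 0.0407, stromal fibroblasts 0.0399, smooth muscle and pericytes 0.0542. With no filter on low values: cytokines and chemokines -0.0153, neutrophils -0.0383. With TPM of at least 5 in 4 libraries: circadian clock 0.0255, stromal fibroblasts 0.0518. With pseudocount 5: theca and interstitial cells 0.00128. With each library left out, the ranges were Ctsl -0.0731 to 0.22, Runx1 -0.0510 to 0.29, Aldh1a1 -0.59 to 0.0246, Acta2 -0.27 to 0.11, Lck -0.0678 to 0.0734, Alas2 -0.0925 to 0.71, Hbb-bs -0.29 to 0.63, steroidogenesis -0.0479 to 0.14, hypoxia response -0.0759 to 0.0778, adhesion and migration -0.0297 to 0.0430, steroid receptors and cofactors -0.0852 to 0.0101, circadian clock -0.0619 to 0.00878, immediate early and heat shock genes -0.25 to 0.00996, interferon response -0.13 to 0.00396, unfolded protein response -0.0659 to 0.0290, mitochondrially encoded genes -0.0351 to 0.0438, theca and interstitial cells -0.13 to 0.0401, stromal fibroblasts -0.12 to 0.0378, smooth muscle and pericytes -0.0882 to 0.0533, neutrophils -0.19 to 0.54, erythroid cells -0.29 to 0.63.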

Other observations

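The tests of Lyve1 in this part were chosen after the result was seen. Several genes among those with the next lowest p, chosen after their values were seen, were lower in PGR-A KO with groups that do not overlap. A choice by low p makes groups without overlap likely, so this is not separate support. Of 28 genes with an unadjusted limma p under 0.001, 26 were lower in KO, so the direction is not particular to these genes. The genes given below did not pass over all genes in the main fit. Myof passed without PGR-A KO replicate 3, and Tmem37 and Fam210b passed without WT replicate 1. Phlda1, Myof, Tmem37, Fam210b and Mertk passed with array weights and with the first residual component, both chosen after their effect was seen. Phlda1 had 7.30 ± 0.542 TPM (SD, n = 4) in KO and 11.9 ± 0.976 TPM (SD, n = 4) in WT (limma adjusted p = 0.251). Myof had 29.0 ± 4.22 and 43.8 ± 0.788 TPM (SD, n = 4; limma adjusted p = 0.332). Tmem37 had 10.7 ± 0.9 and 23.1 ± 6.8 TPM (SD, n = 4; limma adjusted p = 0.332), Fam210b 14.1 ± 0.587 and 30.8 ± 9.84 TPM (SD, n = 4; limma adjusted p = 0.336), and Mertk, a receptor for engulfing dead cells, 9.05 ± 1.05 and 13.5 ± 0.988 TPM (SD, n = 4; limma adjusted p = 0.393). The heat shock gene Hspa1b had 9.55 ± 1.58 TPM (SD, n = 4) in KO and 27.9 ± 12.9 TPM (SD, n = 4) in WT (limma adjusted p = 0.570).

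Lyve1 differed between genotypes by a log2 ratio of mean TPM of -2.87, and a lower number of cells that carry it is a candidate explanation. The 9 tested markers of resident macrophages had a median log2 ratio of -0.20, with a lower quartile of -0.36. This argues against a general loss of macrophages as large as the fall of Lyve1. Mrc1, C1qa, C1qb, C1qc and Csf1r among them are also in the list of macrophages in general, where 10 of 11 markers had lower means in KO. A loss of LYVE1-positive macrophages alone could therefore be hidden, and the values do not decide on it. The 7 tested lymphatic endothelial markers had a median of -0.11 and a lower quartile of -0.17. Pecam1 and Tie1 among them are also in the list of endothelial cells in general. A loss of lymphatic cells could therefore be hidden, and the values do not decide on it. Several of the macrophage and lymphatic markers are near 1 TPM or are made by granulosa cells too (Gas6, at 112 TPM in KO and 128 TPM in WT). Within 5 Mb of Lyve1, 2 of 47 genes had an unadjusted p under 0.05, against 6.33% of 14098 other genes with a position (Fisher's exact p = 0.768, odds ratio 0.66 with a 95% interval from 0.077 to 2.53), which leaves a linked segment open, as are a strain variant at Lyve1 itself and a change of Lyve1 within cells, both untested.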
